A study of Arabidopsis thaliana with 9 samples.

How the data were processed

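NAC103 binding was measured by ChIP in 3 replicates of 35S:NAC103-GFP seedlings and by DAP in 2 replicates of NAC103-Halo on seedling DNA. The 9 samples also include 3 ChIP inputs and 1 DAP input, whose data were not used here as separate lists. Seedling chromatin was fixed with 1% formaldehyde. No untagged or GFP-alone ChIP was used here, so peaks that come from the tag, the antibody or open chromatin are not told apart from NAC103 binding. Per the submitters' processing notes, reads were handled with BWA and MACS2 on TAIR10, with no versions stated. The 5 deposited lists are narrow peaks in the format of the MACS2 peak caller, called for each replicate against input, per the labels.

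For each peak the authors' deposited list gives a score, a fold enrichment over background (a ratio), the −log10 of a p-value and of a q-value, and the distance of the summit from the peak's start. The smallest −log10 q in any list was 1.30, so weak peaks are included. The authors' fold was used to rank, filter and describe peaks within a list, and no change between lists was read from it. Peaks on the mitochondrial and plastid genomes were left out of all comparisons, which left 4187, 14318 and 17074 ChIP peaks and 20746 and 20962 DAP peaks.

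Peaks of 1 assay that overlapped by at least 1 bp were merged into regions. A reproducible ChIP region had a peak in at least 2 of the 3 replicates and a reproducible DAP region in both. The rank of a region was the mean percentile of fold over its replicates, and its anchor was the summit of its best-ranked peak. Coordinates are 1-based and on TAIR10, as in the lists. Gene names came from a RefSeq gene table of the assembly TAIR10.1, which gives no strand and no exons. Its fit to the peaks was checked in 25 segments, 5 per chromosome: in 25 of them ChIP anchors lay within 300 bp outside a gene end more often than after a shift of 2000 bp to either side. Windows of 1000 bp outside to 500 bp inside were planned around gene starts. Without the strand they were set around both ends of each of 27444 nuclear protein-coding genes, so a bound gene can be bound at either end, and an anchor can count for more than 1 gene. The sequence words planned for the anchors need a genome sequence and were not analysed here.

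Overlap shares were compared with 1000 random placements of the regions, of the same width on the same chromosome (one-sided permutation p), and given with exact binomial intervals at 95%, which cover counting error only. The chromosome lengths were the largest coordinates seen. Placements could fall anywhere on a chromosome. Sequence where no peak can be called was not left out, which can lower the chance shares. Fold of DAP regions with and without a ChIP peak was compared by 100000 permutations over regions. Gene lists were tested with two-sided Fisher's exact tests over coding genes and adjusted by the Benjamini-Hochberg method over 12 lists at a threshold of 0.05. All 304 loci of the 11 written lists were found in the gene table, and the NAC family was taken from its names. Among the gene families looked at afterwards, the result of 1 is not reported here. Regions and genes are not replicates, so these tests describe the lists at hand. No test across samples was made.

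Named genes followed a rule fixed before the data were examined. It took NAC103; the 12 highest-ranked genes with a ChIP region in all 3 replicates that overlaps a DAP region; the 6 highest without a DAP peak; the 6 highest DAP genes without a ChIP peak; and up to 4 members of each list bound in both assays, or any bound member of a list that passed. Genes that share an anchor were both named.

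Alternatives fixed in advance were a −log10 q of at least 10, an equal number of top peaks per list (4187), ChIP regions in all 3 replicates, each replicate left out, stricter overlaps (50% reciprocal, or summits within 100 bp), other gene windows, random placements that keep the distance to a gene end, and isolated genes. They used 200 random placements, except that 1000 were used for those that keep the distance, and 10000 permutations.

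The files hold no read counts. Where MACS2 adds 1 to the pileup and to the background before it takes their ratio, the fold and the Poisson p-value together fix the whole-read pileup at the summit and the background. A whole number fitted the deposited −log10 p within 0.01 for 100% of the nuclear peaks of each list, against 12.4% to 26.2% after random shifts of −log10 p. Backgrounds recovered in this way depend on that assumption and on fragment length, and were not read as sequencing depth.

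The calculations were tested on simulated data. Of 13000 simulated regions, the count per number of replicates was off by 0. Of 200 random placements, 1.5% passed the overlap test at 0.05. Random gene lists passed in 2.6% of 1000 cases and lists of raised odds in 100% of 200. These simulated lists were all of the same size and were judged by unadjusted p, so they do not show the power for short lists after adjustment. For 4874 simulated peaks 100% of pileups were recovered. The work was done with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.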

Results

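The series measured where NAC103, an Arabidopsis transcription factor of the NAC family, sits on the genome in 2 kinds of assay. Chromatin immunoprecipitation (ChIP) was made from whole seedlings that carried a NAC103-GFP fusion under the strong 35S promoter. The seedlings were 5 days old and had been kept for 24 h in 20 µM MG132, an inhibitor of the proteasome, because the series design states that the proteasome normally keeps NAC103 at a low level. DNA affinity purification (DAP) used a NAC103-Halo fusion on genomic DNA from seedlings, so that no chromatin was present. The ChIP group had 3 replicates, each with its own input, and the DAP group had 2 replicates that shared 1 input. Each of these 5 samples came with its own list of peaks. The ChIP lists held 4208, 14320 and 17095 peaks for replicates 1, 2 and 3, and the DAP lists held 20792 and 21011. No read totals stand in the lists, so the depth of each library is unknown. Nothing in the labels says that replicates came from separate cultures, so the spread between them may be technical.

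Replicate agreement was the first question. Of the 4187 nuclear ChIP peaks of replicate 1, 86.1% overlapped a peak of replicate 3 and 73.2% a peak of replicate 2, where random placement gave 11.3% and 10.2%. Replicates 2 and 3 shared less of their longer lists: 62.1% of the replicate 2 peaks overlapped replicate 3, against 12.9% by chance. In DAP, 87.8% of the replicate 1 peaks overlapped replicate 2, against 16.1% by chance. Every one of these shares exceeded all 1000 random placements (one-sided permutation p = 0.000999, the smallest they can give). Of the 22435 merged ChIP regions, 12934 (57.7%) had a peak in 1 replicate only, and of the 23389 merged DAP regions 5307 (22.7%). Merging the peaks gave 9501 reproducible ChIP regions (a peak in at least 2 of 3 replicates), of which 2781 had a peak in all 3, and 18082 reproducible DAP regions. Leaving out ChIP replicate 2 left 3520 reproducible ChIP regions and leaving out replicate 3 left 2916, so the larger number rests on these 2 lists. Across shared regions the authors' fold enrichment ranked alike in the DAP replicates (Spearman 0.940, 18082 regions) and less so in the ChIP pairs (0.376 for replicates 1 and 2, 0.488 for 1 and 3, 0.389 for 2 and 3). Regions are not independent replicates, and the DAP replicates share their input, which can add to their agreement.

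ChIP regions gathered at the ends of protein-coding genes. The anchor of a region, its best-ranked summit, fell within 1000 bp outside or 500 bp inside a gene end for 79.7% of ChIP regions (95% exact interval 78.9% to 80.5%), against 48.2% for random placements. For DAP regions the share was 55.6% (54.9% to 56.3%), against 48.2% (permutation p = 0.000999 for both). The median distance to the nearest gene end was 253 bp in ChIP and 598 bp in DAP. DAP anchors instead lay inside coding genes in 64.8% of regions, where the highest of 200 random placements gave 55.0%. The placements also fell in sequence where no peak can be called, so how much of the DAP excesses this explains is unknown. The ChIP share inside genes, 55.2%, lay within the range of its random placements (52.9% to 55.5%), but regions in all 3 replicates lay below theirs (45.3%, range 51.2% to 56.3%). Single ChIP lists also departed from theirs: replicate 1 lay below (44.0%, lowest placement 52.3%) and replicate 2 above (70.2%, highest placement 55.7%). Which end of a gene is its start was not used here, since the gene table gives no strand.

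**Figure D1:**
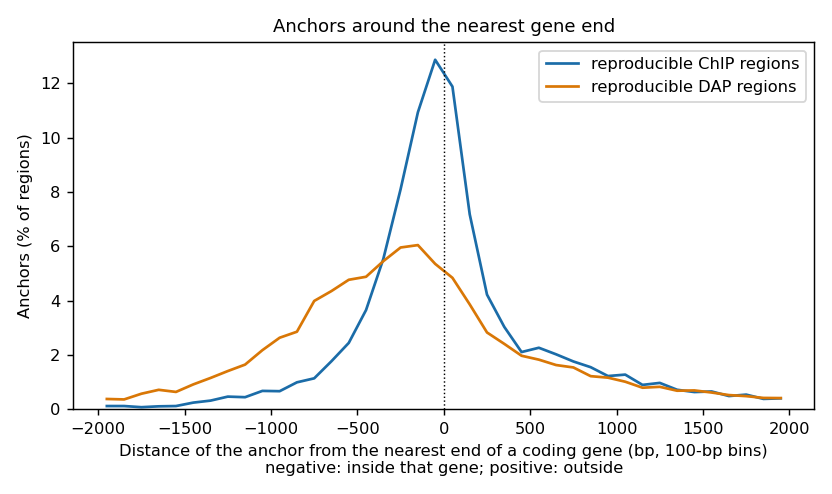
Anchors of reproducible ChIP regions (blue) and DAP regions (orange) by distance from the nearest end of a coding gene in bp, as a percent of regions per 100-bp bin. Negative distances lie inside that gene. The median distance was 253 bp for ChIP and 598 bp for DAP.

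The comparison of the assays asks how far binding in seedlings follows binding to bare DNA. Of the 9501 ChIP regions, 2474 (26.04%, 95% exact interval 25.2% to 26.9%) overlapped a reproducible DAP region, where random placement gave 18.0% on average and 19.3% at most. The share was 31.8% for ChIP regions found in all 3 replicates, against 20.7% by chance, and 23.7% for those found in 2, against 17.0%. Conversely, 14.1% of the DAP regions overlapped a reproducible ChIP region, against 9.64% (permutation p = 0.000999 for both directions). The size of these shares depends on what counts as shared: the ChIP share was 8.55% (chance 4.67%) when regions had to overlap by 50% of each, and 7.90% (chance 2.90%) when summits had to lie within 100 bp. With equal numbers of top peaks per list it was 10.3% (chance 4.57%). When the random placements also kept each region's distance to a gene end, the ChIP share stayed above chance (21.7%, permutation p = 0.000999), but the DAP share did not (chance 13.9%, p = 0.240). The DAP share was 5.18% without ChIP replicate 2 and 5.17% without replicate 3, against 3.42% and 3.14% by chance. DAP regions with a ChIP peak had a median fold of 3.18, against 2.81 without one, a ratio of 1.13 (permutation test, p = 1e-05, the smallest that 100000 resamples can give). Among the replicate 2 ChIP peaks, ranked by fold and parted into 10 equal parts, 43.7% of the top part overlapped a DAP region and 18.16% of the bottom part. These shares were 29.2% and 23.4% in replicate 1, and 25.8% and 18.7% in replicate 3. Neither the fold test nor the ranked parts were matched for width, and a wider region overlaps others more readily. ChIP regions that overlapped a DAP region had a median width of 717 bp, against 545 bp for those without. These values therefore do not tell strength of binding from width. Summits of overlapping regions lay 221 bp apart at the median.

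**Figure D2:**
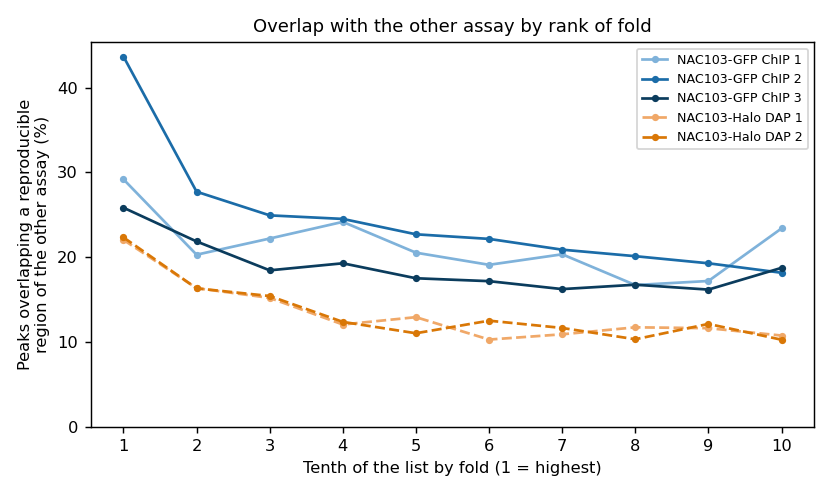
Percent of peaks that overlap a reproducible region of the other assay, for 10 equal parts of each peak list ranked by fold (1 is the highest). Solid blue lines are the ChIP replicates and dashed orange lines the DAP replicates. The top part of ChIP replicate 2 reached 43.7%. The parts were not matched for peak width.

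NAC103 itself was bound in DAP: a region inside the gene with a summit at position 25635779 of chromosome 5 (TAIR10) had folds of 9.95 and 9.33. In ChIP, replicate 3 had 1 peak in the window of NAC103 (fold 2.45), replicates 1 and 2 had none, and no reproducible region was there. Among regions with a ChIP peak in all 3 replicates and a DAP region, the best-ranked gene was SRO3 (AT1G70440), of the family of RCD1-like proteins. Its region on chromosome 1, 26549016 to 26550830, had ChIP folds of 3.78, 11.8 and 8.10 and DAP folds of 11.9 and 10.7. AT4G05380 followed on chromosome 4, 2735835 to 2736767, with ChIP folds of 3.50, 8.71 and 9.06 and DAP folds of 11.03 and 10.7. CIPK23 (AT1G30270), a protein kinase of potassium and nitrate uptake, came next, on chromosome 1, 10658482 to 10659502, with ChIP folds of 3.87, 13.8 and 5.36 and DAP folds of 7.44 and 6.86. The other genes named by this rank were AT1G30660, AT4G12731, AT4G12735 and AT4G12740 (which share 1 anchor), AT3G57760 and AT3G57770, PPX2 and AT5G55270, and MLP168 and AT1G35320, with genes at a shared anchor both named.

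Other high-ranked ChIP regions had no DAP peak in either replicate. LAF3 (AT3G55850) ranked first, with ChIP folds of 4.197, 13.7 and 6.33 on chromosome 3, 20725361 to 20726142. ARLA1D (AT5G67560) shared its anchor with AT5G67550 at folds of 3.799, 18.8 and 6.42, and AT1G70180, AT1G70190 and AT5G26990 completed the first 6. The regions at ARLA1D, at AT1G70180 and AT1G70190, and at AT5G26990 also had an annotated noncoding RNA gene within 1000 bp. The coding genes named are thus not the only neighbours of these peaks. In the opposite class, DAP regions without a peak in any ChIP replicate, the highest lay in AT1G11690 beside AT1G11684, with folds of 31.3 and 30.8. EC1.2 (AT2G21740), a gene of a secreted egg-cell protein, shared its anchor with CAD2 (AT2G21730) at folds of 23.0 and 22.3, and PSRP3/2 with GNA1 at 18.4 and 17.5. In all, 6517 ChIP regions had no DAP peak and 13387 DAP regions had no ChIP peak.

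Of the gene lists fixed before the data were examined, the 26S proteasome list stood out in ChIP. It holds genes of the 26S proteasome, the protease that degrades ubiquitin-tagged proteins, and also PA200, PTRE1, NAC053 and NAC078. ChIP bound 44 of its 55 genes (95% exact interval of the share 67.0% to 89.6%), against 34.3% of all 27444 coding genes (Fisher's exact test, odds ratio 7.70, adjusted p = 5.33e-11). PAD1, an alpha subunit of its core, had ChIP folds of 2.95 and 4.38 in replicates 2 and 3, and PA200, a proteasome activator, 2.05, 4.01 and 4.26 in the 3 replicates. The core subunit genes PBD1, PBD2 and PBF1 and the ATPase gene RPT2a were bound in both assays, RPT2a with DAP folds of 5.87 and 5.37. So was NAC053, itself a regulator of proteasome genes, with ChIP folds of 2.08, 2.64 and 5.09. Of the list of protein folding in the endoplasmic reticulum and its stress response, 22 of 33 genes were bound (66.7%, odds ratio 3.84, adjusted exact p = 0.000985). They included the stress regulators BZIP60, BZIP28 and BZIP17, the chaperone gene BIP2 and the calreticulin gene CRT1a. Heat shock genes were bound in 14 of 20 cases (odds ratio 4.48, adjusted exact p = 0.00432), among them BAG6 and HSP90.1, and autophagy genes in 17 of 26 (odds ratio 3.63, adjusted p = 0.00432), among them ATG8H and ATG2. The nuclear photosynthesis genes, a reference list, also passed, with 20 of 36 bound (odds ratio 2.40, adjusted exact p = 0.0301). A share above that of all genes is thus not particular to the stress lists. The reference share was 55.6%, against 70.0% for heat shock, 66.7% for folding and 65.4% for autophagy, and these were not tested against it. No expression data were used here, so effects of transcription under MG132 are not told apart for any of these lists.

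Leaving out a ChIP replicate ended some of these calls. The proteasome list passed with 16 members bound without replicate 2 (29.1% against 13.5% of all genes, odds ratio 2.63, adjusted exact p = 0.0276). Without replicate 3 it passed with 19 (34.5% against 11.1%, odds ratio 4.26, adjusted exact p = 4.21e-05). The folding list was lost without replicate 2 (odds ratio 2.05, adjusted exact p = 0.132) or 3 (2.17, 0.208). Autophagy and heat shock were lost without replicate 3 (odds ratios 1.91 and 2.68, adjusted exact p = 0.393 and 0.187), and photosynthesis without replicate 2 or 3 (odds ratios 1.03 and 1.00, p = 1 for both). The ranges that follow cover the alternatives that could change a call and gave a finite odds ratio. The adjusted exact p ran from 0.000242 to 0.539 for folding and from 0.000242 to 0.393 for autophagy. It ran from 0.00206 to 0.346 for heat shock and from 0.00922 to 1 for photosynthesis. Other lists passed instead: abscisic acid genes without replicate 2 (12 of 44, adjusted exact p = 0.0408), and the mitochondrial response (6 of 15, 0.0226) and the NAC family (20 of 101, 0.0394) without replicate 3.

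**Figure D3:**
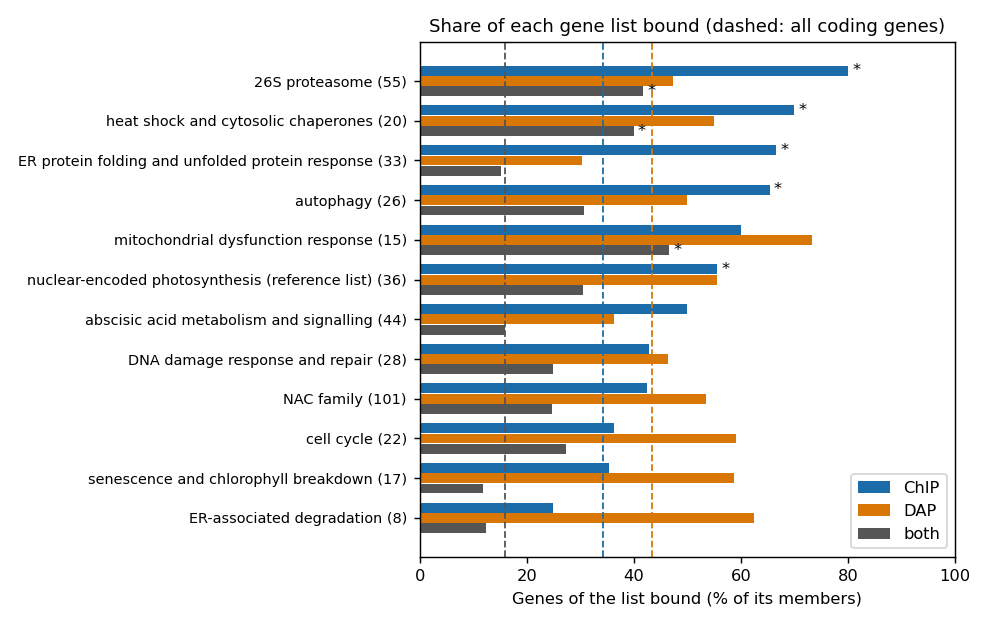
Percent of the members of each gene list bound by ChIP (blue), by DAP (orange) and in both assays (grey); the number of members stands in parentheses. Dashed lines give the shares of all coding genes (34.3%, 43.5% and 15.9%), and asterisks mark an adjusted p under 0.05 by Fisher's exact test.

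Genes bound in both assays numbered 4356, against 4089 for independent sets of 9406 ChIP-bound and 11931 DAP-bound genes (Fisher's exact test, odds ratio 1.19, p = 8.02e-12). Of the 12 lists, 3 were over-represented among them. The list of the response to failing mitochondria had 7 of 15 genes bound in both (46.7% against 15.9% of all genes, odds ratio 4.64, adjusted exact p = 0.0299). AOX1A, the alternative oxidase, had ChIP folds of 1.95, 4.06 and 3.50 and DAP folds of 2.82 and 3.22 on chromosome 3, 7906285 to 7907497. CRF6 had ChIP folds of 2.74, 3.86 and 4.801, and the other members were ERF71 (HRE2), TIM17-1, NDB2, UGT74E2 and AT2G21640 (UPOX). The proteasome list had 23 of 55 genes bound in both (odds ratio 3.82, adjusted exact p = 4.72e-05) and the heat shock list 8 of 20 (odds ratio 3.54, adjusted p = 0.0334), HSP90.1 among them with DAP folds of 10.03 and 10.9. A gene bound in both need not have its ChIP and DAP anchors at the same end. The HSP90.1 summits lay at 21355398 in ChIP and 21352834 in DAP, and the ERF71 regions did not overlap. Without ChIP replicate 2 the proteasome call was lost (6 of 55, odds ratio 1.80, adjusted exact p = 0.391). Heat shock was lost without replicate 2 (odds ratio 3.68, adjusted exact p = 0.105), where its odds ratio was no lower, and without replicate 3 (odds ratio 1.98, 0.576). The number of genes bound by ChIP fell to 3716 without replicate 2 and to 3037 without replicate 3, and that bound in both to 1750 and 1458. The mitochondrial list passed whichever replicate was left out, and 5 lists passed without ChIP replicate 1 or without DAP replicate 2. Among genes bound by DAP no list passed, and 2 had an unadjusted Fisher's exact p under 0.05: the mitochondrial list (11 of 15, p = 0.0334) and the NAC family (54 of 101, p = 0.0446). DAP bound 26 of 55 proteasome genes (47.3% against 43.5% of all genes, adjusted exact p = 0.642). It bound 11 of 20 heat shock genes (55.0%, adjusted exact p = 0.491). A list bound often by ChIP can pass in both assays without a preference in DAP. The calls of these 2 lists in both assays therefore do not show one.

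The remaining lists did not pass in ChIP, in DAP or in both assays. DNA damage genes were bound in both assays in 7 of 28 cases (adjusted exact p = 0.291), led by AT5G02220 (SMR4), NAC085, TSO2 and AT1G07500 (SMR5). SMR4 had ChIP folds of 2.65, 6.44 and 3.92 on chromosome 5, 441871 to 442771. Cell cycle genes were bound in both in 6 of 22 cases (adjusted exact p = 0.2495), led by ICK1 (KRP1), MYB3R-4, LGO and FZR2. ICK1, an inhibitor of cyclin-dependent kinases, had ChIP folds of 2.19, 4.24 and 5.14 and DAP folds of 7.05 and 7.28. Genes of abscisic acid were bound by ChIP in 22 of 44 cases (adjusted exact p = 0.0750) and in both in 7, led by PYL5, PP2CA, CYP707A1 and GEA6. Of 17 senescence genes 6 were bound by ChIP, 10 by DAP and 2 in both, NYE1 and SAG101. Of 8 genes of degradation from the endoplasmic reticulum 2 were bound by ChIP, 5 by DAP and 1 in both, UBC32 (adjusted exact p = 1 in both assays for these 2 lists). The NAC family had 25 of 101 members bound in both (adjusted exact p = 0.0536), led by NAC049, NAC050, NAC085 and NAC047.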

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

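The following tests of this part were chosen after the result was seen: ChIP-only against DAP-only members, the overlap with DAP at proteasome genes, the comparison of proteasome with ribosomal protein genes under the alternatives, and the background of the strongest peaks.

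The assays differed in which members of 2 lists they bound. Of the proteasome genes bound in 1 assay, 21 were bound by ChIP and 3 by DAP, against 5029 and 7572 of other genes (Fisher's exact test, odds ratio 10.5, adjusted p = 2.48e-05). Of the genes of protein folding in the endoplasmic reticulum, 17 were bound by ChIP alone and 5 by DAP alone (odds ratio 5.11, adjusted exact p = 0.00376). Without ChIP replicate 2 the odds ratios were 2.597 and 3.71 (adjusted exact p = 0.126 and 0.129), with 10 proteasome genes bound by ChIP alone and 20 by DAP alone. Without replicate 3 they were 3.75 and 4.16 (adjusted exact p = 0.0379 and 0.119), with 9 and 16. Over all 13 alternatives run, 8 passed for each list. The proteasome odds ratio was at least 2.48 in all of them. The folding odds ratio turned to 0 with a −log10 q of at least 10, where 0 members were bound by ChIP alone and 7 by DAP alone. Peaks on the organelle genomes, which no comparison used, numbered 21 in ChIP replicate 1 and 21 in replicate 3 (2 in replicate 2), and 46 and 49 in DAP replicates 1 and 2. No control list was used here to set them against.

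Background at strongly transcribed genes was weighed as the source of the proteasome result. Ribosomal protein genes, a strongly transcribed class written down before the test, were bound in ChIP in 38.2% of 34 cases. This was below the lower bound of the proteasome share (67.0%), which argues against transcription in general as its full source in this window. The classes were not matched for gene length, and a gene under 500 bp has a smaller window. The photosynthesis genes, the reference list, were bound in 55.6% of 36 cases, also below that bound but over the 34.3% of all genes. A partial contribution was therefore not excluded. Without ChIP replicate 2 the ribosomal and proteasome shares were 11.8% and 29.1% (lower bound 17.63%, Fisher's exact p = 0.0702 between the classes), and without replicate 3 they were 8.82% and 34.5% (lower bound 22.2%, p = 0.00606). With ChIP regions in all 3 replicates they were 11.8% and 27.3% (lower bound 16.1%, Fisher's exact p = 0.112). With the window of 500 bp outside and 0 bp inside, whose size does not depend on gene length, they were 29.4% and 38.2% (lower bound 25.4%, exact p = 0.494). This window therefore does not bear the argument out. No window excludes a rise of proteasome gene transcription under MG132, since no expression data were used here. A direct sequence preference stayed open: 35.0% of the 60 ChIP regions at proteasome genes overlapped a DAP region, against 26.4% of other gene-bound ChIP regions (Fisher's exact test, p = 0.142). DAP by itself bound 47.3% of the 55 proteasome genes, against 43.5% of all genes (Fisher's exact test, odds ratio 1.17, adjusted p = 0.642). No preference for the list was thus found on bare DNA.

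Of the 20 best-ranked regions with a peak in all 3 replicates, 10 lay over 1000 bp from any coding gene, 7 of these within 1000 bp of an annotated pseudogene, and 9 of the 10 overlapped a DAP region. The first, on chromosome 2, 3531957 to 3533371, had ChIP folds of 12.7, 48.0 and 39.0 and DAP folds of 11.4 and 12.9. The recovered background at these 10 summits was at most 1.38 times the list's median, but the regions were picked by fold, which falls as the background rises, so this value says nothing against collapsed repeats. That explanation stayed open. No biological explanation was tested.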

How the results depend on the processing

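The overlap of ChIP with DAP regions, the anchors in gene-end windows of both assays and the DAP fold ratio kept their direction and stayed past the threshold under every alternative run for them, but the overlap shares changed in size. The DAP to ChIP overlap did so too, except with random placements that keep the distance to a gene end, where 14.1% met a chance of 13.9% (permutation p = 0.240). The DAP to ChIP share was 3.47% (chance 1.90%) with 50% reciprocal overlap and 2.85% (chance 1.04%) with summits within 100 bp. It was 2.88% (chance 1.49%) with a −log10 q of at least 10, 8.94% (chance 3.93%) with equal numbers of top peaks and 5.32% (chance 3.33%) with ChIP regions in all 3 replicates. With a −log10 q of at least 10 there were 1112 ChIP regions, 1144 genes bound by ChIP, 553 bound in both and 3 lists over-represented in ChIP. The median Spearman correlation was then 0.538 in ChIP and 0.924 in DAP, and the odds ratio was 0 for heat shock in both assays and for protein folding and photosynthesis in ChIP, since no member was left. With equal numbers of top peaks there were 3171 ChIP and 3713 DAP regions, 3279, 2877 and 435 genes bound by ChIP, by DAP and in both, 0 lists in both assays and 2 in ChIP, and the photosynthesis odds ratio turned to 0.670. ChIP regions in all 3 replicates gave 2781 regions, 2999 genes bound by ChIP, 1438 in both, and 1 and 2 lists in both and in ChIP. Summits within 100 bp gave 6141 ChIP regions. The wider window, of 2000 bp, gave 7469 genes bound in both. The window of 500 bp outside gave 4227, 4183 and 754 genes bound by ChIP, by DAP and in both, and the proteasome odds ratio in both assays turned to 0.655. Among the 2289 isolated genes, few of which are list members, 0 lists passed in both assays and 0 in ChIP. The cause of these moves was not tested beyond the smaller lists.

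Leaving out each replicate in turn gave 2916 to 9501 ChIP regions, 3037 to 9406 genes bound by ChIP, 1458 to 4861 bound in both, and 1 to 5 and 3 to 5 lists in both assays and in ChIP. The values of 9501 and 9406 come from leaving out a DAP replicate, which cannot change the ChIP counts. The lowest counts of regions and genes came without ChIP replicate 3. Of the list calls, that of the proteasome in ChIP passed in all 11 alternatives that could change it and gave a finite odds ratio, with odds ratios from 2.63 to 10.3 and adjusted p from 1.04e-12 to 0.0276. It did not pass among the isolated genes, where 0 lists passed in ChIP. In both assays the mitochondrial list passed in 11 of 14 and the proteasome list in 10 of 14.

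The added alternatives were chosen after seeing the data. Giving each anchor to its nearest gene end left 2428 genes bound in both and 1 list in DAP, the NAC family (49 of 101, adjusted exact p = 0.0103). Asking that the ChIP region itself overlap a DAP region left 2830 genes. The whole gene with 1000 bp on each side, and leaving out peaks of high recovered background, moved no count by over 1.5 times. The sequence word results and their window were not run, and the isolated genes were taken from both gene ends, since starts are not known. No paired analysis was possible because the results come from no test across samples, and ChIP and DAP replicates share only numbers. Depth limits are unknown, as the lists hold no read totals.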

Other observations

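Gene families outside the fixed lists were looked at after the data were seen, by taking the 96 symbol stems with at least 15 coding genes. The ERF stem, mostly transcription factors of the ethylene response, had 19 of 25 genes bound by ChIP (76.0% against 34.3% of all genes, Fisher's exact test, odds ratio 6.08, adjusted p = 0.00117). DAP bound 7 of 25 (28.0% against 43.5% of all genes, adjusted exact p = 0.707). In 5 of 25 a ChIP region overlapped a DAP region (adjusted exact p = 0.642), so the ERF result was seen in ChIP only. ERF4 had ChIP folds of 2.31, 5.04 and 5.49, and ERF104 had 4.15 in both replicates with a peak. ERF1-1 and ERF1-2 under the same stem are translation release factors, of which ChIP bound ERF1-2. The PUB stem, U-box ubiquitin ligases, had 15 of 22 genes bound by ChIP (odds ratio 4.11, adjusted exact p = 0.0210), and 10 of 22 had at least 1 ChIP region in their window that overlapped a DAP region (odds ratio 7.27, adjusted p = 0.00258). PUB22, PUB18, PUB9 and PUB29 were among these. The summits lay close together for PUB18 (3484391 in ChIP and 3484357 in DAP) and PUB9 (2356890 and 2356856), but not for PUB22 (19442694 and 19441011). For PUB29 the ChIP region from 6435236 to 6436014 did not itself overlap the DAP region from 6434266 to 6434676. The HSP stem passed in the same 2 tests (17 of 23, adjusted exact p = 0.00443, and 9 of 23, p = 0.0133), and it shares members with the heat shock list. Other stems were bound less often: UMAMIT, amino acid transporters, in 3 of 44 genes (adjusted exact p = 0.00124), and LCR, small cysteine-rich proteins, in 9 of 80 (adjusted p = 0.000424), with LCR also low in DAP (17 of 80, adjusted p = 0.00366). SCRL genes were also bound less often in ChIP (adjusted exact p = 0.0263). These stems were not run under the alternatives.

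Peaks of ChIP replicate 2 lay inside coding genes more often (70.2%) than those of replicates 1 (44.0%) and 3 (52.9%), and 83.1% of the 5260 peaks found in replicate 2 alone did so (95% exact interval 82.1% to 84.1%). Both tests of this pattern were written before their results. A longer list of weak peaks was 1 possible explanation. With the 4187 top peaks of each list, replicate 2 still exceeded the higher of the others by 14.0 percentage points, over the bound of 5 set beforehand, so list length alone does not account for it. Signal over the bodies of strongly transcribed genes stayed open. Ribosomal protein genes held a summit of replicate 2 alone 1.78 times as often as genes of like length (26.5% against 14.8%), over the factor of 1.5 set beforehand, but with a permutation p of 0.0517 over 10000 draws of 34 genes. No biological explanation was tested.

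The background recovered at the summits had a median of 32.5, 23.7 and 19.4 reads in ChIP replicates 1, 2 and 3 and 47.2 and 49.3 in DAP. It lay within 0.01% of the lowest value of the list in 97.4% and 97.1% of the DAP peaks, and in 25.9%, 18.5% and 50.7% of the ChIP peaks.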
